A study of Mus musculus with 12 samples.

How the data were processed

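H3K27ac Hi-ChIP was carried out on hepatocytes of male C57BL/6 mice. The assay combines proximity ligation with immunoprecipitation of histone H3 acetylated at lysine 27, a mark of active promoters and enhancers, so that it recovers contacts between regions that carry the mark. The 12 libraries fall into 2 groups of 6, young mice aged 5 months and old mice aged 25 months, each with 2 biological replicates in 3 batches of technical repeats. Per the labels' protocols, livers were perfused and digested with collagenase, and hepatocytes were pelleted at low speed and used after removal of red blood cells. That pellet could hold some other liver cells, so marker lists for 5 such cell types were included.

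The authors deposited 1 interaction network per age, in 4 tables. No replicate or batch is named for either network, so each was taken to pool the libraries of its age. How the libraries were combined is not given in the sources used here. Per the file headers, 1 table of each age lists the nodes of the network with their positions, and the other lists the cliques of nodes with the number of nodes, the genes attached to each clique and the node names. On inspection every node was a 5 kb bin, every node belonged to exactly 1 clique, and every clique held at least 2 nodes. The deposited gene column gives either gene names or the entry for a clique without a promoter. Bowtie2 and HiC-Pro are named in the submitters' processing notes, with the builds mm10 and GRCm38 and without versions. The loop caller, its thresholds, the method that formed the cliques and the promoter window are not given in the sources used here. The word clique is the authors': links between nodes were not analysed here, so whether every pair of nodes in a clique is linked was not examined. With up to 193 nodes and each node in exactly 1 clique, these sets have the form of communities that divide a network rather than of complete subgraphs, and clique size below means the number of nodes in such a set. The number of sequenced reads and of valid contacts behind each network is unknown, and a network from fewer contacts would be expected to hold fewer nodes.

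Because each age is represented by 1 pooled network, no spread between animals or batches could be computed and no p-value is given. Values describe these 2 networks. Confidence intervals are Wilson 95% intervals for a share of nodes or cliques. They cover counting error only and treat nodes or cliques as independent, which neighbouring ones are not.

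Nodes of the 2 ages were matched by position, with a minimum overlap of 1 bp, which on the shared 5 kb grid means the same bin. Chance overlap was taken from 100 random circular shifts of the old network along each chromosome. The size of a clique is its number of nodes. For each pair of a young and an old clique the Jaccard index is the number of shared nodes divided by the number of nodes in either, and the best index of each clique was kept. For each gene, the size of the largest clique that lists it in the deposited gene column was taken at each age, 0 if no clique did, and the old value was set against the young as log2((old + 1)/(young + 1)). A gene at 0 at one age is described as listed in no clique of that age, and no fold is given for it. Of the 16197 gene names in either network, 15717 were found in the table of gene symbols and 9611 matched a protein-coding gene of the RefSeq annotation of GRCm38.p6, by symbol or by a unique synonym, giving 9596 genes. Gene coordinates are from that annotation, 1-based, on the same assembly as mm10. A promoter window of 2500 bp around transcription start sites had been planned. The gene table used here has no strand, so the authors' gene column took its place, as provided for in the plan.

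Before the data were examined, 16 pathway lists and 5 cell type lists were fixed. For every list with at least 5 listed members, the median log2 value was ranked among 10000 random lists of the same size, drawn within deciles of mean clique size over both ages. The percentile is a description of the 2 networks. Genes that share a clique have the same value, so list members are not independent.

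The genes named in the text follow a rule fixed at the same time. They are up to 4 protein-coding genes of each of the 10 largest cliques of each age, members of the fixed lists first; the 10 genes with the largest gain and the 10 with the largest loss in log2 clique size, 1 per pair of young and old cliques; and the up to 4 members of each list with the largest absolute log2 value. The largest gains and losses among genes listed at both ages were added after the data were seen. Any other gene is said to have been chosen after its values were seen. Some genes that the rule names are not reported here.

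The list percentile was tested on simulated data made by permuting the log2 values of the 6257 genes listed at both ages. Of 200 lists of 20 genes with no effect, 6 lay outside the central 95%. Of 10 lists lowered by a factor of 1.5, 5 lay below it, and of 10 lowered by a factor of 2, all 10 did. Permuting gives genes that share a clique different values, and genes not listed at both ages were left out. These counts therefore do not show how the percentile behaves for lists that hold such genes. As a check of the code alone, all 34156 nodes kept at random from the young network and all 393 cliques divided in it were recovered. No node was lost where cliques were divided, so this check does not cover loss and division together.

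Alternatives fixed before the data were examined were a reciprocal overlap of 50%, cliques of at least 3 or 10 nodes, autosomes only, covered length or genomic span in place of size, random thinning of the young network to the node number of the old in 10 draws, a gene-span assignment (any node within a RefSeq gene or 2500 bp on either side), a pseudocount of 5, sizes divided by the mean of the age, unmatched random lists, and all annotated protein-coding genes as background. Lists with 1 gene per pair of cliques, genes listed at both ages, and thinning for the gene lists were added after the data were seen. Analyses used Python 3.11.15, pandas 2.3.3, NumPy 2.4.6 and SciPy 1.17.1, and figures were drawn with matplotlib 3.10.9.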

Results

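Contacts between chromatin regions carrying H3K27ac were mapped by Hi-ChIP in hepatocytes of male mice aged 5 months (young) and 25 months (old), 6 libraries per age from 2 biological replicates. Each age was represented by 1 pooled network of 5 kb nodes grouped into cliques, so the comparisons below have no replicate check and no p-value. The number of reads behind each network is unknown. The comparisons ask which regions, cliques and genes of the enhancer and promoter network differed between young and old hepatocytes.

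The old network held fewer nodes than the young on all 20 chromosomes. It had 40304 nodes covering 201.52 Mb, against 56928 nodes covering 284.64 Mb in the young network, which is 29.2% fewer. The ratio of old to young nodes ran from 0.597 on the X chromosome to 0.792 on chromosome 17. Most of the old network lay inside the young: 31640 nodes were shared, which was 78.5% of the old nodes (95% Wilson interval 78.1 to 78.9) and 55.6% of the young (55.2 to 56.0). Circular shifts of the old network gave 4731 shared nodes on average and 5613 at most. A further 25288 nodes were listed only in the young network and 8664 only in the old. On the X chromosome 63.1% of the 336 old nodes were shared, compared with 75.6% to 81.9% on the autosomes. Young nodes in large cliques were more often present in the old network than those in small ones. The share was 67.1% for cliques of 50 or more nodes and 22.5% for cliques of 2 nodes.

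Large cliques were fewer in the old network than in the young, and the very large ones were rarest. The young network had 200 cliques of 50 or more nodes and 17 of 100 or more, and the old network had 58 and 3. Cliques of 50 or more nodes held 24.7% of young nodes and 9.60% of old nodes. The mean clique had 10.5 nodes in young and 6.75 in old, the median 3 and 2, and the largest 193 and 160. The median genomic span was 95 kb in young and 55 kb in old. The old network listed more cliques in all, 5973 against 5401, because it had 2992 cliques of 2 nodes against 2286. With at least 3 nodes required the order turned, with 3115 young and 2981 old cliques. Cliques that listed at least 1 gene were 63.6% of young (62.3 to 64.9) and 61.3% of old (60.03 to 62.50).

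**Figure D1:**
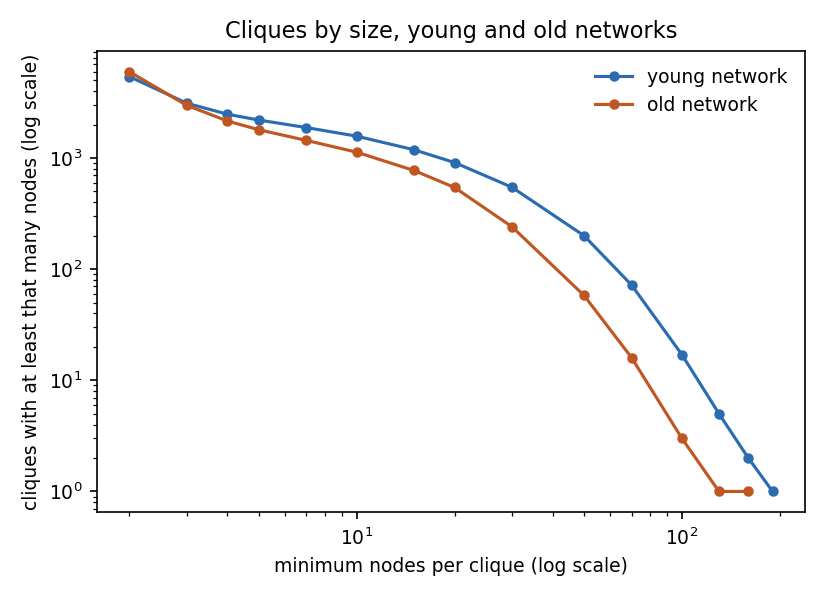
Number of cliques (vertical axis, log scale) with at least a given number of nodes (horizontal axis, log scale) in the young network (blue) and the old network (orange). The old network has more cliques of 2 or more nodes, 5973 against 5401, and fewer of 50 or more, 58 against 200.

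Several of the largest young cliques had part of their nodes in several smaller old cliques, and the rest were absent from the old network. The largest young clique had 193 nodes on chromosome 3 from 121155001 to 122645000 and listed Rwdd3, Alg14, Cnn3 and Abcd3, the last a peroxisomal fatty acid transporter. Of its nodes 123 (63.7%) were present in the old network, in 6 cliques, the largest with 77 nodes. The third largest, 159 nodes on chromosome 10 from 127350001 to 128540000, listed the glutaminase gene Gls2, the interferon signalling gene Stat2 and the activin subunit genes Inhbe and Inhbc. Of its nodes 102 (64.2%) lay in 8 old cliques, where Inhbe and Inhbc were listed with 69 nodes and Gls2 and Stat2 with 11. Cyp2e1, an ethanol- and drug-oxidising cytochrome P450, was listed in a young clique of 148 nodes on chromosome 7 and an old clique of 5. Cpt1a, which controls fatty acid entry into mitochondria, was in a clique of 126 nodes in young and 24 in old, and the stress-response transcription factor gene Atf3 in cliques of 120 and 12.

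Some of the largest old cliques had the opposite order, with nodes of several smaller young cliques in 1 old clique. On chromosome 7 from 18895001 to 19970000, the second largest old clique had 121 nodes, of which 95 lay in young cliques of 98, 12 and 4 nodes. It listed Foxa3, a hepatocyte pioneer transcription factor, which was in a clique of 12 nodes in young. It also listed Apoe, the gene of a lipoprotein component, together with Fosb, both in cliques of 98 nodes in young. The third largest old clique, 116 nodes on chromosome 17 from 55955001 to 57340000, listed the complement gene C3 and the lipid droplet gene Plin5, which were in young cliques of 30 and 67 nodes. Other large cliques were of like size at both ages. Gadd45b was in cliques of 185 and 160 nodes, Jund and Gdf15 in cliques of 84 and 81, and Epas1 in cliques of 99 and 96, and these 4 genes had the larger value in old once sizes were divided by the mean of the age or the young network was thinned.

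**Figure D2:**
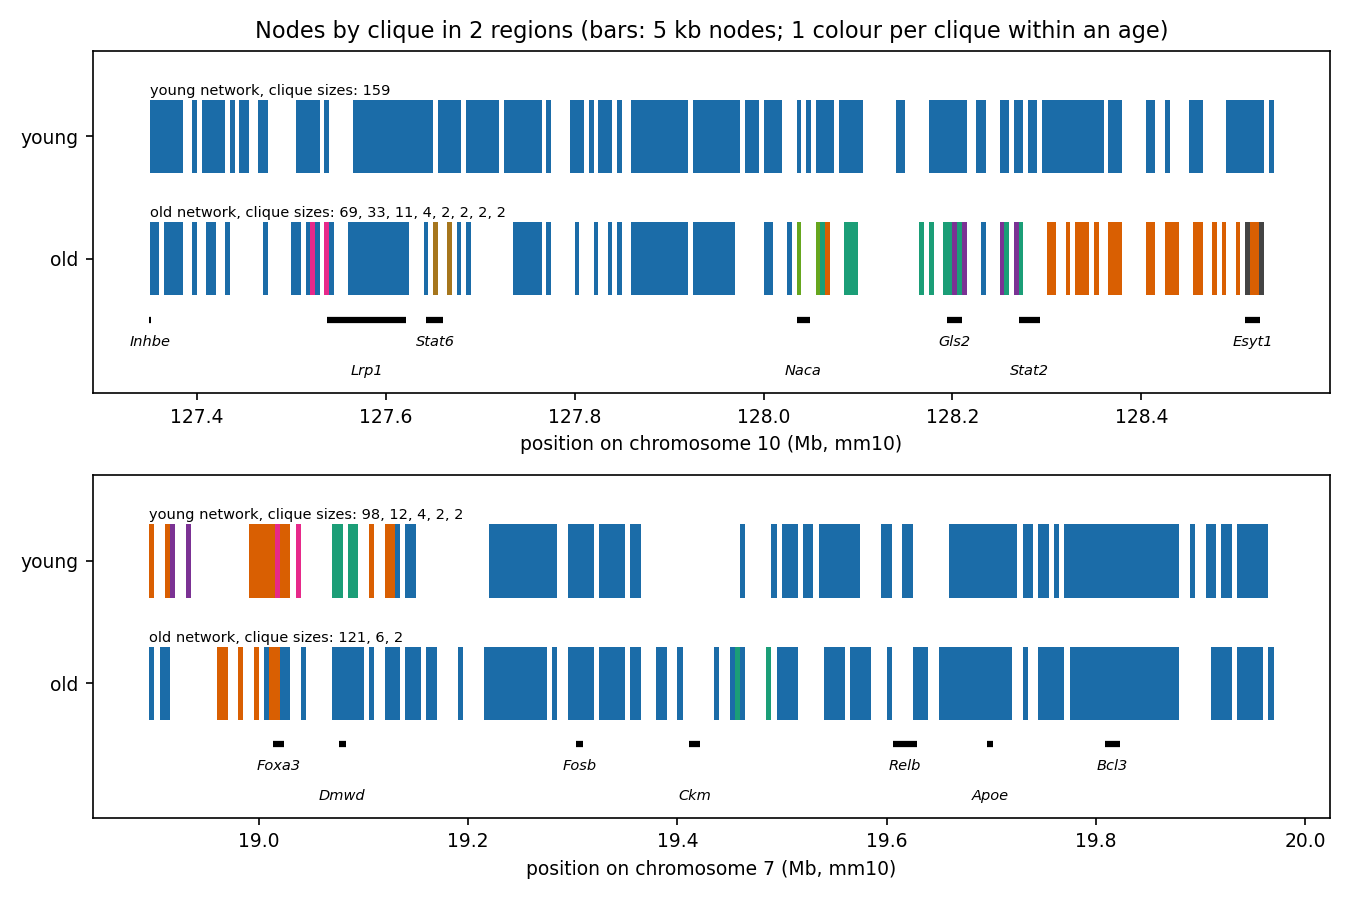
Nodes (bars of 5 kb, coloured by clique within each age) along chromosome 10 and chromosome 7 in mm10 coordinates (horizontal axes, Mb), with the young network above the old and genes as black lines. On chromosome 10, 102 nodes of a young clique of 159 lie in old cliques of 69, 33, 11 and fewer nodes. On chromosome 7, 95 nodes of an old clique of 121 lie in young cliques of 98, 12 and 4 nodes.

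Across the genome, 2064 of the 5401 young cliques (38.2%, 36.9 to 39.5) shared no node with the old network, and 1317 of the 5973 old cliques (22.0%, 21.02 to 23.12) shared none with the young. Circular shifts gave 77.4% and 75.3%. Young cliques were more often spread over several cliques of the other age: 1223 of them (22.6%) shared nodes with 2 or more old cliques, and 673 old cliques (11.3%) with 2 or more young ones. Young cliques were also larger on average, and these shares were not matched on clique size. A best Jaccard index of at least 0.5 was reached by 1071 cliques of each age, 19.8% of young and 17.9% of old, against 0.251% and 0.227% on average in the shifts. Of the cliques with 50 or more nodes, 96 of the 200 young and 39 of the 58 old reached it.

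Genes followed the cliques. Of 9596 protein-coding genes listed in either network, 8690 were listed in young and 7163 in old, with 6257 in both, 2433 in young only and 906 in old only. Among genes listed at both ages the median clique size was 30 nodes in young and 16 in old. The clique was smaller in old for 5100 of these genes, larger for 811 and equal for 346. Over all listed genes, 7533 had the lower value in old and 1717 the higher, with a median log2 value of -0.93. Dividing sizes by the mean of each age gave 5622 genes lower and 3974 higher in old, with a median of -0.22. There 1 was added after the division, which draws values toward 0, and a pseudocount of 5 alone gave -0.58. Thinning the young network gave 5589.4 lower and 3298.5 higher. A thinned clique kept all its listed genes while 2 of its nodes remained, so thinning did not equalise gene listing. Many genes listed at 1 age still had a node of the other age in or near the gene. Of the 2433 genes listed in young only, 1195 (49.1%) had an old node within the gene or 2500 bp of it, compared with 18.2% of genes listed at neither age.

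The largest losses were of genes listed in large young cliques and in no old clique. Slc44a3, a choline transporter-like gene (chromosome 3, 121459528 to 121532344), was listed in the young clique of 193 nodes and in no old clique, with an old clique of 35 nodes in its gene span. Amh, which encodes anti-Mullerian hormone, was listed in the young clique of 185 nodes and in no old clique, although an old clique of 160 nodes reached its gene span. Atp5b, a mitochondrial ATP synthase subunit gene, was in a young clique of 159 nodes and in no old clique, with an old clique of 11 nodes in its gene span. Mdm4, a p53 regulator gene, was in a young clique of 112 nodes and had no old node in its gene span. In the other direction, the ion channel gene Hcn2 was listed in the old clique of 160 nodes and in no young clique, with a young clique of 8 nodes in its gene span. The creatine kinase gene Ckm was listed only in the old clique of 121 nodes, although no old node lay within 2500 bp of the gene, and Dennd1c only in that of 116, with a young clique of 30 nodes in its gene span. Among genes listed at both ages, Esyt1, Nab2 and Naca were in cliques of 159 nodes in young and 2 in old, with 33 nodes in old by gene span for Esyt1. Fgfbp3 was in cliques of 2 and 76 nodes, Dmwd in cliques of 4 and 121, and the ubiquitin-conjugating enzyme gene Cdc34 in cliques of 8 and 160.

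Of 20 hepatocyte transcription factor genes 19 were listed at both ages, and 19 had the smaller value in old, Hnf4a among them with no old clique. The median was 47 nodes in young and 26.5 in old. With sizes divided by the mean of the age, 8 were larger in old and 12 smaller, and after thinning 7.3 and 12 on average. Hnf4a, a central regulator of hepatocyte identity, was listed in a young clique of 65 nodes, with an old clique of 25 nodes in its gene span. Foxa3 was the exception, at 12 nodes in young and 121 in old. Nr2f6 was in cliques of 40 and 9 nodes and Hhex in cliques of 15 and 3. Genes of secreted plasma proteins had medians of 36.5 and 20.5 nodes, and 18 of 20 had the smaller value in old, 2 of them in no old clique, against 9 with sizes divided by the mean of the age and 9.8 after thinning. F2, encoding prothrombin, was in a young clique of 77 nodes and in no old clique, with 4 nodes by gene span, and Plg, encoding plasminogen, was in cliques of 50 and 11. Apoe and Ambp were the 2 with larger old cliques. Alb, which encodes albumin, was at 60 and 41 nodes. Ambp and Alb were chosen after their values were seen.

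All 18 listed genes of xenobiotic metabolism and all 16 of glucose metabolism had smaller values in old, with medians of 47 and 16 nodes in the first group and 28.5 and 12.5 in the second. With sizes divided by the mean of the age, 4 xenobiotic genes were larger in old and 14 smaller, and 7 glucose genes were larger and 9 smaller. After thinning the averages were 3.1 and 13.5, and 4.6 and 10.5. Cyp2c37 and Cyp2c50, both cytochromes P450, were in a young clique of 13 nodes and in no old clique, and the carboxylesterase gene Ces2a was in cliques of 63 and 4 nodes. In glucose metabolism, Gys2, the liver glycogen synthase, was in cliques of 30 and 2 nodes, and Tat in cliques of 41 and 12. For fatty acid oxidation and PPAR-alpha targets, 14 of 19 had the smaller value in old, 4 of them in no old clique, and 4 the larger, and relative to the mean of the age 10 were smaller and 9 larger. Fgf21, a hormone of the fasting response, was in cliques of 72 and 2 nodes, and Cidec was in a young clique of 67 nodes and in no old clique, with an old clique of 43 nodes in its gene span. Plin5 was among the 4 with larger old cliques.

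Bile acid genes were smaller in old in 13 of 16, among them Cyp27a1, which starts the alternative synthesis pathway, at 85 and 2 nodes, and Cyp7b1 at 29 and 2. Lipid synthesis genes had the smaller value in 19 of 22, but with sizes divided by the mean of the age 15 were larger and 7 smaller, and after thinning 10.4 and 10.2 on average. Acaca, an acetyl-CoA carboxylase gene, was in a young clique of 30 nodes and in no old clique, with 7 nodes by gene span. Fasn (120 and 77 nodes) and Sqle (117 and 78) stayed in large cliques, and their log2 values were slightly above 0 when sizes were divided by the mean of the age. In amino acid metabolism, 15 of 20 had the smaller value in old and 5 the larger. Tdo2, a tryptophan-degrading enzyme, was in a young clique of 23 nodes and in no old clique, and Agxt, a peroxisomal aminotransferase, was in cliques of 3 and 40. Clock genes had the smaller value in old in 11 of 17, the larger in 3 and an equal one in 3. Hlf, Npas2 and Tef were listed in young cliques of 45, 40 and 31 nodes and in no old clique, with old cliques of 24, 3 and 27 nodes in their gene spans. Genes of growth hormone signalling and male-biased expression had the smaller value in 12 of 14, including Stat5b, the hormone's signal transducer, and the male-biased Cyp2d9. These 2 were in young cliques of 60 and 63 nodes and in no old clique, with old cliques of 18 and 28 nodes in their gene spans. Relative to the mean of the age, the genes smaller in old were 9 of 16 for bile acids, 11 of 20 for amino acid metabolism, 10 of 17 for the clock and 11 of 14 for growth hormone.

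The p53 and interferon lists held 4 and 5 genes listed in old only, the most of the 16 pathway lists. In the p53 and cell cycle arrest list, 13 of 17 genes were listed in young and 16 in old, and 12 had the smaller value in old and 5 the larger. Zmat3 and Tnfrsf10b, both p53 targets, were in old cliques of 8 and 10 nodes and in no young clique, although a young clique of 9 nodes reached the gene span of Tnfrsf10b, while Bbc3 was in cliques of 62 and 3 nodes (37 in old by gene span) and Cdkn2c in cliques of 24 and 2. In the interferon list, 15 of 20 were listed in young and 19 in old, and 13 had the smaller value in old and 7 the larger. Here H2-D1, a class I histocompatibility gene, was in an old clique of 20 nodes and in no young clique. Oasl2 was in an old clique of 46 nodes and in no young clique, although a young clique of 55 nodes reached its gene span. Psmb9 was in cliques of 49 and 2 nodes. Usp18 was in a young clique of 103 nodes and in no old clique, with an old clique of 45 nodes in its gene span. Acute phase genes had the smaller value in 15 of 20, among them Apcs (22 and 2 nodes) and Crp (22 and 3). AP-1 and immediate early genes had it in 14 of 18, with Jun at 39 and 13 nodes and Ier5 at 27 and 5. Among senescence-associated secretory factors 10 of 13 had the smaller value as listed, but with sizes divided by the mean of the age 9 were larger and 4 smaller, and after thinning 7.1 and 5.6 on average. Tgfb1 was in cliques of 48 and 2 nodes (14 in old by gene span), and Tnf and Cxcl9 were listed only in old, in cliques of 20 and 41, with a young clique of 112 nodes in the gene span of Cxcl9. In the NF-kappaB list 9 of 11 had the smaller value, with Tlr2 at 35 and 6 nodes, while Relb was listed only in the old clique of 121 nodes and a young clique of 98 reached its gene span. Relative to the mean of the age, the genes smaller in old were 4 of 17 for p53, 8 of 20 for interferon, 9 of 20 for acute phase, 8 of 18 for AP-1 and 6 of 11 for NF-kappaB.

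**Figure D3:**
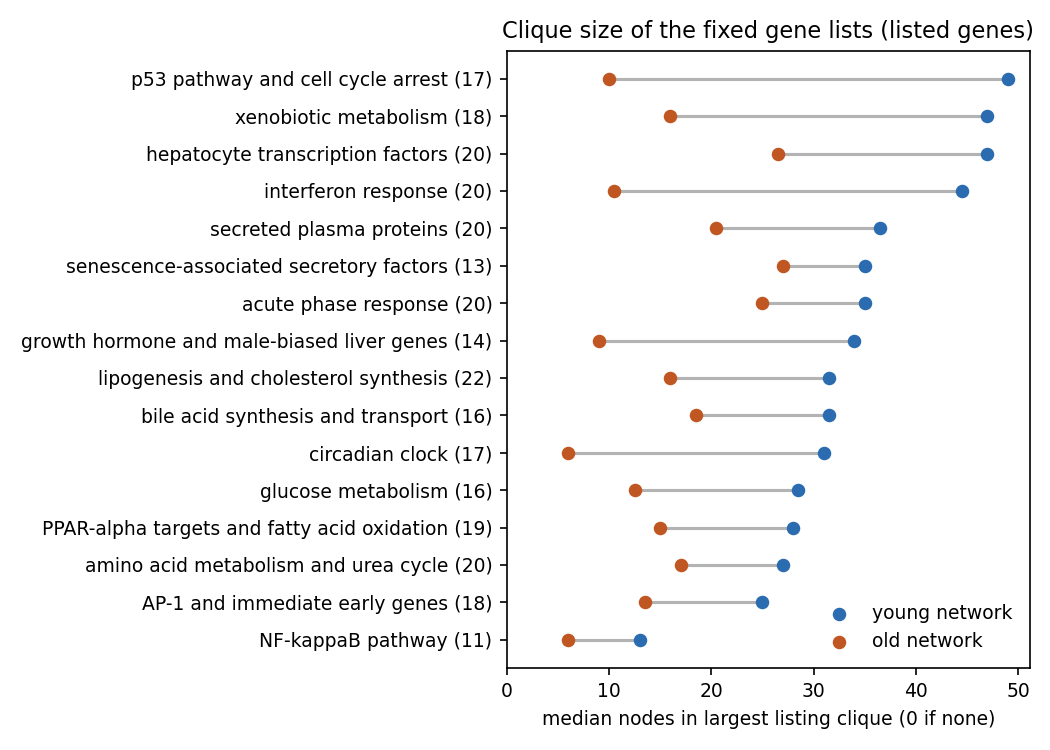
Median number of nodes in the largest clique listing a gene (horizontal axis, 0 for a gene in none) for the listed members of 16 fixed gene lists (vertical axis, number of genes in brackets) in the young network (blue) and the old network (orange). The old median is the smaller in every list, from 49 against 10 nodes for the p53 list to 13 against 6 for the NF-kappaB list. The medians are not paired by gene, so gaps between them can differ from the change by gene. The median log2 value by gene was -0.38 for the p53 list and -0.31 for the interferon list (44.5 and 10.5 nodes).

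The median log2 value was below 0 in all 16 pathway lists, as in the network as a whole. Relative to random lists of like clique size, lipogenesis and cholesterol synthesis (median -0.38, percentile 97.8) and interferon response (-0.31, percentile 97.8) lay just above the central 95%, where 0.8 of 16 lists would be outside by chance. Both lay within it with unmatched random lists, by gene span, after thinning and among genes listed at both ages. In that last setting interferon response was at percentile 36.95 with a median of -0.75. Both lay above it with 1 gene per pair of cliques. AP-1 and immediate early genes followed at percentile 96.4. Acute phase response was at 91.7 (46.8 with 1 gene per pair of cliques, as some members share cliques, Orm and Saa genes among them). The p53 list was at 91.7, secreted plasma proteins at 88.0 and secretory factors at 84.0. The percentiles were 70.2 for glucose metabolism, 68.4 for bile acids, 66.7 for NF-kappaB, 66.2 for hepatocyte transcription factors, 66.2 for fatty acid oxidation and 65.8 for amino acid metabolism. The lowest were the circadian clock at 47.7, xenobiotic metabolism at 35.4 and growth hormone genes at 30.2. By gene span the clock list was at 82.3 (median -0.46), NF-kappaB at 30.1 and fatty acid oxidation at 39.0, so the order of these lists depends on how genes are assigned. With sizes divided by the mean of the age, 7 of the 16 medians were above 0, those of the plasma protein, acute phase, lipogenesis, p53, secretory factor, AP-1 and interferon lists, and with the young network thinned 6 were, the same lists without plasma proteins.

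Markers of other liver cells were seldom listed. Of 57 markers 12 (21.1%) were listed at either age, 10 in young and 8 in old, compared with 281 of 332 pathway genes (84.6%). Of all 21887 annotated protein-coding genes, 9596 were listed at either age. The listed markers included Cx3cr1, a macrophage receptor, in a young clique of 29 nodes and in no old clique. They also included Cldn4, a cholangiocyte claudin, in an old clique of 39 nodes and in no young clique. The endothelial markers Gata4 and Lyve1 were in cliques of 35 and 25 nodes and of 25 and 3. Spp1 was in a young clique of 11 nodes and in no old clique, and the stellate cell gene Pdgfra in cliques of 6 and 4. The lymphocyte marker Cd4 lay in the gene-dense clique of 119 nodes in young and in a clique of 60 in old, with 36 protein-coding genes listed in the young clique. Each of the 5 lists had fewer than 5 listed members, so no percentile is given for listed genes.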

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

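Thinning for the gene lists, 1 gene per pair of cliques and restriction to genes listed at both ages were chosen after the data were seen. No paired analysis was possible because each age is 1 pooled network, and leaving out a replicate was not possible for the same reason. Windows of 1000 bp and a single transcription start site per gene were not run, since the gene table has no strand. A reciprocal overlap of 50% moved nothing, because nodes of both ages lie on 1 grid. The mean clique size and the median gene value were the smaller in old under every alternative run, and so was the node number, except under thinning, which sets node numbers equal. Values for nodes and cliques moved mainly through the removal of small cliques. The share of old nodes also moved under thinning, which lowers it by construction. Values for genes and lists also moved in settings that remove no clique or gene. Among these were division by the mean of the age, which moved the median gene value, and unmatched random lists. Depth limits the whole comparison, since the contacts behind each network are unknown.

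With nodes of cliques of at least 3 nodes, 53.6% of young and 81.8% of old nodes were shared. With the young network thinned, 55.5% of old nodes were. Random removal of young nodes brings this share to about the 55.6% of young nodes shared as listed. Thinning therefore does not test how far the old network lay inside the young. Requiring at least 3 nodes left 3115 young and 2981 old cliques with means of 16.8 and 11.5 nodes, and at least 10 nodes left 1572 and 1128 with means of 28.7 and 23.0. The ratio of mean sizes was 0.64 as listed, 0.706 after thinning and 0.73 by genomic span. For cliques of at least 3 nodes, 29.1% of young and 10.4% of old shared no node, and 25.6% and 26.7% reached a Jaccard index of 0.5. By gene span, 9499 genes had a node at both ages. With sizes divided by the mean of the age, the median log2 value was -0.22 and 3974 genes had the higher value in old. The number was 1717 as listed and 3298.5 after thinning. Both settings lower young sizes relative to old ones by construction. Among the 6257 genes listed at both ages 811 had the higher value in old. That set leaves out the genes listed in old only, all of which count as higher.

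Of the 16 lists, 2 lay outside the central 95% as reported, 0 with unmatched lists, 1 by gene span, 1 against all annotated genes, 3 with 1 gene per pair of cliques, 0 among genes listed at both ages and 0 after thinning. The 3 were lipogenesis (99.5), interferon (98.9) and AP-1 (98.8), and the 1 by gene span was acute phase response (97.565), with lipogenesis at 97.48 and interferon at 97.42. With 1 gene per pair of cliques acute phase response went from percentile 91.7 to 46.8 and its median from -0.44 to -1.22. By gene span 2 cell type lists had enough members, lymphocytes (percentile 49.2) and sinusoidal endothelial cells (85.3). The interferon list moved from percentile 97.8 to 36.95 among genes listed at both ages, so its place rests on the genes listed at 1 age. Of 180 named genes, 20 changed sign with sizes divided by the mean of the age and 11 after thinning, all from smaller to larger in old, the direction in which both settings shift genes by construction. By gene span 6 changed sign, all from larger to smaller in old. A pseudocount of 5 cannot change a sign.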

Other observations

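The tests and gene families in this part were chosen after the data were seen, as were genes that the naming rule does not cover. The interferon and p53 lists had been fixed before. Cytochrome P450 genes, which encode oxidising enzymes for drugs, steroids and fatty acids, had the lowest place of 12 families grouped by gene symbol. Of 49 listed members 47 had the smaller value in old and 1 the larger, and the median clique had 26 nodes in young and 3 in old. Of these members 17 (34.7%) were listed in young only, against 25.4% of all listed genes, and 0 in old only. Their median log2 value was -1.58, at percentile 3.365 of random lists. It stayed below 0 with sizes divided by the mean of the age (-0.44) and after thinning (-1.19). Medians below 0 were found in 11 of the 12 families in the first setting and in all 12 in the second. Over all listed genes the medians were -0.22 and -0.41. All 15 listed UDP-glucuronosyltransferase genes, which conjugate drugs and bilirubin, had the smaller value in old (medians 71 and 28 nodes), 4 of them in no old clique. So did all 10 listed clade A serpin genes (45 and 18.5), 2 of them in no old clique. Members of these families lie side by side in the genome and often share a clique.

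Complex I subunit genes had medians of 29.5 and 3 nodes, with 30 of 34 smaller in old, and cytosolic ribosomal protein genes had 22.5 and 5, with 51 of 64 smaller. Relative to the mean of the age these were 22 and 38 smaller, against 39 of 49 cytochromes P450, 34 of 44 histones, 17 of 32 proteasome subunits, 124 of 210 zinc finger genes, 99 of 195 solute carriers and 4 of 6 Nop genes. Mitochondrial ribosomal protein genes lay higher, at percentile 97.305, and their median was -0.49 as listed, 0.10 with sizes divided by the mean of the age and -0.07 after thinning. Solute carriers, with 146 of 195 smaller in old, were at percentile 98.2 and were the 1 family of 12 outside the central 95%, where 0.6 would be by chance. Glutathione S-transferases (12 of 16 smaller in old) were at percentile 50.3, histones (36 of 44) at 85.4, proteasome subunits (22 of 32) at 76.6 and zinc finger genes named Zfp (153 of 210) at 91.6. For clade A serpins the percentile was 61.7, for UDP-glucuronosyltransferases 30.3, for complex I 15.9, for cytosolic ribosomal proteins 37.0 and for Nop genes of ribosome biogenesis (5 of 6) 58.7.

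The smaller old network was weighed first. Loss on a few chromosomes is argued against by the 20 of 20 chromosomes with fewer old nodes. Single nodes missing at random from otherwise unchanged cliques are argued against as well, since 46.4% (44.5 to 48.3) of the 2635 young cliques with at least 2 shared nodes had them in 2 or more old cliques, against 18.2% of 3705 old cliques with theirs in 2 or more young ones. The shares for young and old cliques were not matched on clique size. Loss of nodes with cliques formed anew from the rest was not tested. Fewer sequenced contacts in the old libraries cannot be told apart from age: 14.2% of old 2-node cliques joined bins over 100 kb apart against 20.1% of young, a direction that shallower data could give, while 21.5% of old nodes lay outside the young network, and with 1 network per age the difference between networks of like age is unknown. An effect of age itself stays open and untested.

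Young nodes at the ends of protein-coding genes were present in the old network more often (66.4%) than nodes inside genes (54.7%) or outside them (49.7%), and the share went from 46.0% in megabases with 0 to 5 protein-coding genes to 67.9% in those with 41 or more. Larger cliques at gene ends do not account for the difference between gene ends and nodes outside genes, since gene ends were retained more often than nodes outside genes in 6 of 6 classes of clique size. The values by gene density were not split by clique size. A candidate explanation is that nodes at gene ends recur in any pair of networks, since nodes listed only in old also lay at gene ends less often (17.6%, 16.8 to 18.4) than shared nodes (23.5%, 23.1 to 24.0). Nodes listed only in young did so in 14.9%. A loss with age of contacts away from gene ends stays open and untested.

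Interferon genes listed in old only, among them H2-D1 and Oasl2, were 5 of 20, against 9.44% of all listed genes, and 3.67% of random lists had as many. The p53 list had 4 of 17 (Btg2, Mdm2, Tnfrsf10b and Zmat3), as many as 6.63% of random lists, but 3 of these 4 had a young clique in the gene span (112 nodes for Btg2, 46 for Mdm2 and 9 for Tnfrsf10b). Chance may account for both, since 31.6% of sets of 16 random lists held 1 as extreme as the interferon list. Of the 5 interferon genes, 4 had no young node within the gene or 2500 bp of it. A promoter bin added inside a young clique can be neither shown nor excluded for the 5. The old clique shared a node with a young clique reaching over the gene for 1 of the 5 (20%, 3.62 to 62.4). For all 906 genes listed in old only the share was 39.0%. An effect of age stays open and untested.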
